A study of Homo sapiens with 4 samples.

How the data were processed

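RNA of 4 cell strains was measured, 1 sample per array: SKBR-3 with an LMO2 overexpression cassette, SKBR-3 with an EGFP control cassette, ZR-75-1 with the EGFP control and ZR-75-1 with an LMO2 knockdown cassette. Per the labels' protocols, cells were exposed to lentivirus for 24 hours, selected with 2 µg/mL puromycin from 3 days after infection and kept at 1 µg/mL until harvest. Total RNA was extracted with Trizol, and double-stranded cDNA was labelled with Cy3 through random 9mer primers by Klenow fragment, so each array carries 1 dye. The deposited table holds 1 intensity per feature and array on a linear scale, made with RMA per the submitters' processing notes. RMA combines background correction, quantile normalization across arrays and a robust summary of probes; its version and settings are not given in the sources used here. The 4 columns have similar medians, but their values are not identical after sorting. All 4 columns were used. Groups were taken from the labels, and replicate numbers name single arrays only.

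Features carry transcript accessions. The platform annotation named 18188 features, all with 1 symbol and 0 with several, and a further 678 were named through an unversioned RefSeq accession in the RefSeq gene table of assembly GRCh38.p14, used for names only. Another 26167 features stayed unnamed here and entered no gene count, among them 6042 with model transcript accessions, 2087 with curated mRNA accessions and 10859 with cDNA clone accessions. Older symbols were updated through the synonyms of that table. The 17185 named genes included 1349 with more than 1 feature, and each was represented by the feature with the highest mean over the 4 arrays. Values of different features were not compared with each other.

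Intensities were taken to log2, and each comparison is the difference of 2 log2 values. With 1 array per group no test was possible, so genes were counted by a fixed rule of size. A gene counted as higher or lower where its ratio was at least 2-fold and the higher of its 2 intensities was at or above the 60th percentile of all features on that array. That level minimum was an intensity of 708 for the overexpression array, 717 for the SKBR-3 control, 684 for the ZR-75-1 control and 693 for the knockdown. As a measure of how far a ratio lies from those of genes of like level, its distance from the median of the 500 genes nearest in mean level was divided by their robust SD. That spread holds real differences as well as noise. Both treated strains were compared with the control of their line, and the controls with each other. The overlap of both treated comparisons, which share no array, was set beside n1 × n2 / N for independent lists.

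The choices in this paragraph were made before the data were examined. Beyond LMO2, the text names the 12 largest increases and 12 largest decreases counted per comparison, up to 4 members per gene list by size of ratio, and up to 10 genes counted in both treated comparisons in the same and in opposite directions. Uncharacterised, antisense and readthrough symbols were counted but not named, and some genes that the rule would name are not reported here. The lists numbered 31 and held 738 symbols, of which 726 were on the array under a name. They cover LMO2 partners, Wnt targets and pathway components, Arp2/3 and actin turnover, oestrogen response, HER2, luminal and basal markers, mesenchymal genes, mitosis, replication, p53, interferon, NF-κB and chemokines, MHC class I and II, unfolded protein and integrated stress response, heat shock, immediate early genes, hypoxia and glycolysis, cholesterol, fatty acids, TGF-β and BMP, Notch, endothelial and haematopoietic genes, immune and fibroblast markers, ribosomal proteins, oxidative phosphorylation, histones and housekeeping genes. A list's value is the median log2 ratio of its members above the level minimum, for lists with at least 3 such members. It is given with its percentile among 10000 random lists of the same size matched on mean level in 10 bins. A list in the lowest or highest 2.5% of random lists was called apart, which 5% of lists of independently varying genes would be by chance. Genes of a real list can vary together, and some genes are in more than 1 list, so more lists could stand apart without an effect of the treatment. Alternatives were quantile normalization of the 4 columns, loess of the ratio on mean level with a span of 0.3, no level minimum, the 80th percentile as minimum, thresholds of 1.5-fold and 3-fold, the mean over the features of a gene, a threshold of 3 local SDs, random lists without matching, and the mean of a list in place of the median. Outside these choices, the 512 genes of families typical of other tissues, further list members and some genes of the line checks were chosen after values had been seen.

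The counting and list steps were tested on simulated data with the local spread of each comparison, with 200 genes changed by known folds. For SKBR-3, over 7844 genes, the rule recovered 20.9% of genes changed 1.5-fold, 77.6% of those changed 3-fold and 100% of those changed 8-fold. Of 100 unchanged lists 5 were called apart, and of 100 lists shifted by 0.5 on the log2 scale 78 were found. For ZR-75-1, over 7520 genes, the rule recovered 8.96%, 98.5% and 100% of those genes, 7 of 100 unchanged lists were called apart and 100 of 100 shifted lists were found. Simulated genes varied independently, so the shares of unchanged lists called apart do not cover lists whose genes vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 (lowess) and matplotlib 3.10.9.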

Results

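Gene expression was measured in 2 human breast cancer cell lines with 1-colour microarrays, each hybridised with the RNA of 1 sample. SKBR-3 is a line with an amplified ERBB2 (HER2) gene, and ZR-75-1 is a line classed as luminal and oestrogen receptor positive. Stable strains had been made by lentiviral infection and puromycin selection. SKBR-3 cells carried a cassette for overexpression of LMO2 or an EGFP control cassette, and ZR-75-1 cells carried a knockdown cassette with an shRNA against LMO2 or the EGFP control. LMO2 is a LIM-only protein that has no DNA-binding domain of its own and joins transcription factors into complexes in blood and endothelial cells. The design set each treated strain against the control of its own line, to ask how the transcriptome differed with more or less LMO2. There was 1 array for each of the 4 groups, so there were no replicates, no p-value could be given, and the number of arrays limits the precision of every value. Each array gave 45033 features, of which 18866 were named and stood for 17185 genes. The median normalized intensity was 455 for SKBR-3 with LMO2 overexpression, 475 for the SKBR-3 control, 442 for the ZR-75-1 control and 452 for the ZR-75-1 knockdown.

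LMO2 itself was dim on all 4 arrays. Its intensity was 145 with overexpression and 67.4 in the SKBR-3 control, a log2 ratio of 1.10. In ZR-75-1 it was 35.3 in the knockdown and 206 in the control, a log2 ratio of -2.54. The knockdown value lies below the 5th percentile of the features of its array, 45.9, so the size of that ratio is not settled. The values ran in the direction of the labels, but on a feature this dim it is a weak check of both labels. Against the 500 genes nearest in mean level, the log2 ratio lay 1.44 robust SDs (local SDs) from their median in SKBR-3 and -3.63 in ZR-75-1. LMO2 lay at percentiles 25.3, 10.7, 32.4 and 1.68 of the features of the overexpression, SKBR-3 control, ZR-75-1 control and knockdown arrays, below the level minimum on each, so it was not counted as changed. A single feature measured it, and where that feature lies in the transcript is not known here, so it may miss the transcript of the overexpression cassette.

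In SKBR-3, the array with LMO2 overexpression had 996 genes counted as higher and 566 counted as lower than the control, of 7844 genes above the level minimum. Among the largest increases, PTDSS1, a phosphatidylserine synthase gene, had an intensity of 2044.51 against 64.4 in the control, AHSG, a liver plasma protein gene, 2601 against 129, and the ribosomal protein gene RPL35A 11051 against 464. The ZR-75-1 control and knockdown values were 5452 and 4575 for PTDSS1, 426 and 310 for AHSG and 6812 and 4860 for RPL35A. The SKBR-3 control array thus had the lowest value of each of these genes, so a value peculiar to that array may underlie their ratios. Ratios with a dim value on 1 array, such as the control values of PTDSS1 and AHSG, are uncertain in size and rank. Further large increases were in SMAP2 (log2 ratio 3.97), TSNAX (3.33), ZNF248 (3.28), RAE1 (3.23), DOP1B (3.23), NSUN2 (3.12), MLXIP (2.99) and PLS1 (2.94). The largest decrease was in RIT2, a small GTPase gene known from neurons, with an intensity of 92.2 against 3966 in the control. CSRP1 and VCL, both genes of the actin cytoskeleton, were lower by log2 ratios of -4.76 and -3.67, HCFC1 by -4.18 and the tubulin gene TUBB by -3.66. SCUBE2 (-3.36), JAKMIP2 (-3.33), BIN2 (-3.29), LCN10 (-3.10), MT4 (-3.05) and ZNF410 (-2.94) were also among the largest decreases.

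**Figure D1:**
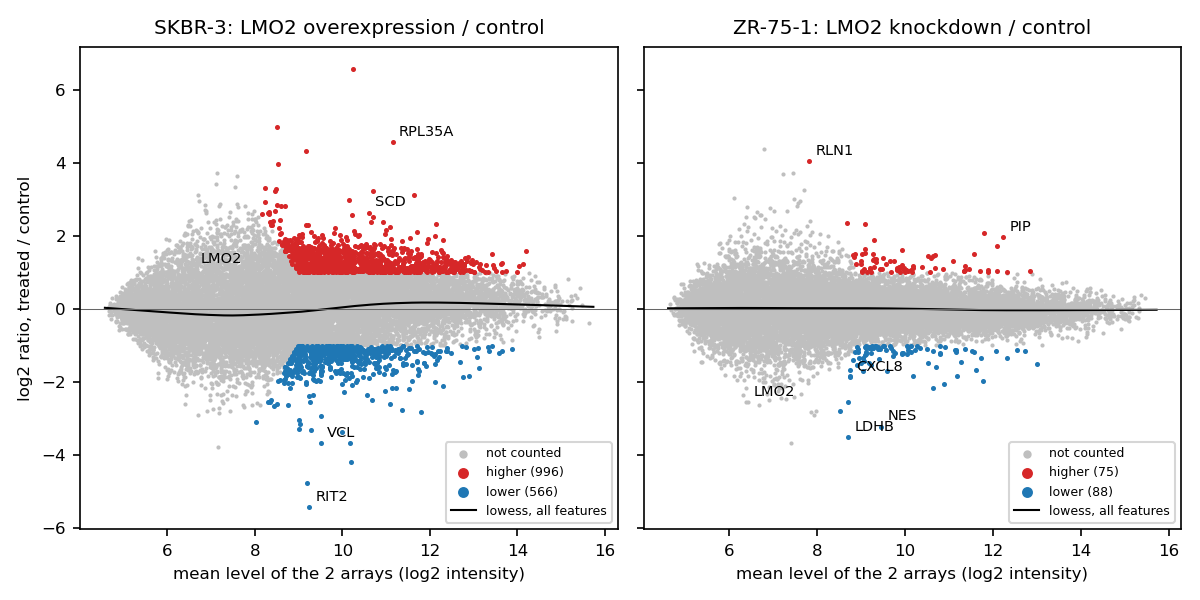
Each point is 1 gene, with the mean log2 intensity of the 2 arrays on the x axis and the log2 ratio of treated over control on the y axis, for SKBR-3 (left) and ZR-75-1 (right). Red and blue points are genes counted as higher (996 and 75) and lower (566 and 88), grey points are not counted, and the black line is the lowess trend over all features.

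Genes of lipid synthesis and of hypoxia and glycolysis were among the groups higher in SKBR-3 with LMO2 overexpression. Of 12 measured genes of fatty acid synthesis and lipid metabolism, 5 were counted as higher and 1 as lower. The stearoyl-CoA desaturase gene SCD had an intensity of 3867 against 620.4, a log2 ratio of 2.64, ACSS2, which makes acetyl-CoA from acetate, had a ratio of 2.16, and the fatty acid synthase gene FASN 1.58. FABP5 was lower, at -1.30. The list's median log2 ratio was 0.74, at percentile 99.2 of random gene lists matched on level, but at 83.7 without a level minimum. Of 21 genes of hypoxia and glycolysis, 6 were counted as higher and 0 as lower. These included the histone demethylase gene KDM3A (1.45), the carbonic anhydrase gene CA9 (1.38), NDRG1 (1.31) and the prolyl hydroxylase gene P4HA2 (1.27), and the list's median of 0.87 lay above all 10000 random lists. Of 18 genes of cholesterol synthesis and LDL uptake, 5 were counted as higher and 1 as lower. LSS (1.68), CYP51A1 (1.58) and MVK (1.57), all enzymes of the sterol pathway, had the largest ratios, but the list's median of 0.56 at percentile 94.6 did not stand apart. The median over all genes above the level minimum was itself 0.27, so the medians of the fatty acid, hypoxia and cholesterol lists lay 0.47, 0.60 and 0.29 above it. The housekeeping genes, a list meant not to move, also stood apart, with a median of 0.59 at percentile 98.4, 0.32 above that of all genes, and 2 of 14 counted as higher, YWHAZ (1.47) and PPIA (1.30). Without matching on level the housekeeping list lay at percentile 94.2.

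In SKBR-3, 5 lists stood apart as lower. Of 8 measured immune cell markers, 5 were counted as lower, among them AIF1 (-1.38), the B-cell gene CD79A (-1.30) and GNLY (-1.10), and CD68 (1.23) was higher. Their median was -1.05 at percentile 0.12. Of 13 NF-κB targets, cytokines and chemokines, 0 were counted as higher and 2 as lower, the acute-phase genes SAA2 (-1.68) and SAA1 (-1.35), and the median was -0.30 at percentile 1.46, but -0.50 as a mean and -0.72 with the 80th percentile minimum. SAA1 and SAA2 are near-identical genes whose features may read each other. Of 13 Wnt/β-catenin target genes, 1 was counted as higher, TCF7L2 (1.66), and 0 as lower, and FOSL1 (-0.92), NOTUM (-0.91) and NKD1 (-0.87) were not counted. The median of the Wnt targets was -0.45 at percentile 0.445, and with a level minimum at the 80th percentile it was 0.17 at percentile 32.7, no longer apart. Of 4 genes of the endothelial and haematopoietic list, ENG (1.22) was counted as higher and BCL2 (-1.21) and TAL1 (-1.21) as lower. The list's median was -0.72 at percentile 0.76. With the mean over the features of a gene it was -0.23 at percentile 17.0, and BCL2 is a gene with 2 features. The 14 genes of MHC class I and antigen presentation had 0 counted as higher and 1 as lower, ERAP2 (-1.16). The next furthest from 0, not counted, went in both directions: TAPBP (0.96), TAP2 (0.88) and PSMB9 (-0.75). Their median of -0.06 lay at percentile 1.58, or -0.33 relative to all genes above the level minimum, and at 8.78 without matching on level.

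Beside all of these SKBR-3 lists stands a measured difference in genes of families typical of other tissues. Over 512 genes of olfactory and taste receptors, hair keratin-associated proteins, late cornified envelope proteins, β- and γ-crystallins of the lens and beta-defensins, the median intensity was 265 on the SKBR-3 control array. It was 155 on the overexpression array, 159 on the ZR-75-1 control array and 154 on the knockdown array. Not all of these genes were dim, as between 60 and 110 of them lay at or above the level minimum of an array. The median log2 ratio of these genes was -0.74 in SKBR-3 and 0.01 in ZR-75-1, and 52 of them were among the 566 genes counted as lower in SKBR-3.

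**Figure D2:**
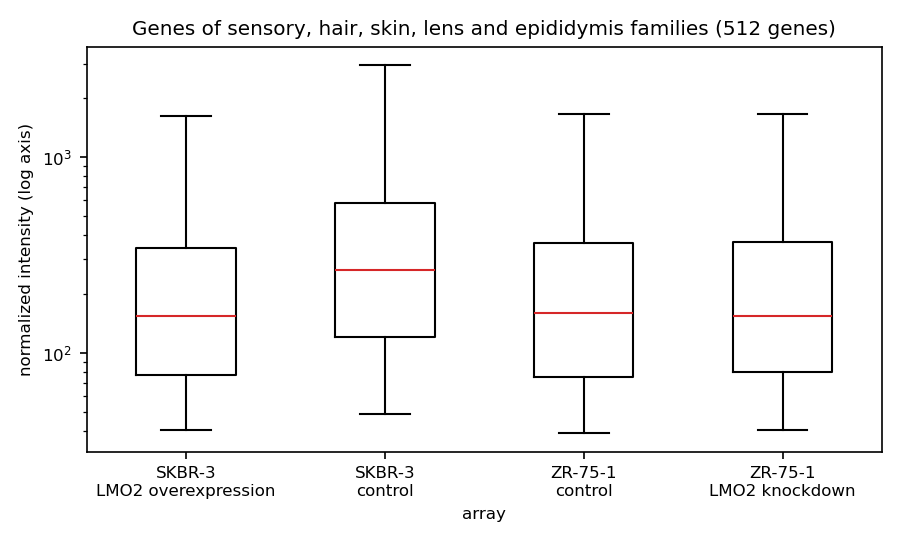
Boxes show the normalized intensity, on a log axis, of 512 genes of sensory receptor, hair, skin, lens and defensin families on each of the 4 arrays, with the median in red, quartiles as box edges and whiskers from the 5th to the 95th percentile of genes. The SKBR-3 control box has a median of 265, above the medians of 155, 159 and 154 on the other arrays.

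The remaining lists did not stand apart in SKBR-3. Of 15 Wnt pathway components, 5 were counted as higher and 1 as lower. β-catenin (CTNNB1, 1.65), the kinase gene GSK3B (1.28), DVL2 (1.22) and PORCN (1.08) were higher, and the median was 0.33 at percentile 62.6. Of 25 genes of the Arp2/3 complex, profilin and actin turnover, ACTR2 (1.28) and DIAPH3 (1.01) were higher and the cortactin gene CTTN (-1.64) was lower, with a median of 0.28 at percentile 54.5. Of 14 genes of the HER2 amplicon and signalling, EGFR (1.44), GRB7 (1.24) and ERBB3 (1.18) were higher, with a list percentile of 59.9. Of 22 mitosis genes, 4 were higher, TPX2 (1.15), BUB1 (1.15), MKI67 (1.09) and CCNA2 (1.04), at percentile 50.7, and after loess the ratios of TPX2, MKI67 and CCNA2 were 0.99, 0.99 and 0.93, under the threshold. Of 22 replication genes, POLA1 (1.58) and RFC3 (1.29) were higher, at percentile 95.2. Of 23 genes of the unfolded protein and integrated stress response, HSPA5 (1.90), DNAJC3 (1.75) and PDIA4 (1.25) were higher, at percentile 79.7. Of 12 p53 targets, CCNG1 (2.29) and DDB2 (1.18) were higher and PHLDA3 (-1.78) was lower, at percentile 75.2. Of 18 immediate early genes, 3 were higher and 2 lower, among them EGR1 (1.35) and FOSB (-1.78), at percentile 49.3. Of 8 Notch pathway genes, RFNG (1.31) and NOTCH3 (1.14) were higher and HEY1 (-1.71) was lower, at percentile 19.99.

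Smaller counts were found in the other SKBR-3 lists. Of 11 interferon-stimulated genes, STAT2 (1.55) and USP18 (1.44) were higher, at percentile 83.0. Of 12 oestrogen response genes, MYB (1.66) and CELSR2 (1.49) were higher, at percentile 45.1. Of 17 luminal markers, 2 were higher, among them ELF5 (1.20), at percentile 38.9. Of 14 basal markers, CNN1 (-1.33), KRT5 (-1.30) and SOX10 (-1.17) were lower and EGFR was higher, at percentile 17.4. Of 6 mesenchymal genes, COL6A2 (2.61) and ITGA5 (1.47) were higher, at percentile 25.8. Of 12 TGF-β and BMP targets, CCN2 (1.62) and LTBP1 (1.04) were higher, at percentile 57.7. Of 13 heat shock chaperones, AHSA1 (1.499) and BAG3 (1.00) were higher, at percentile 29.9. Of 10 LMO2 partners and LIM-only genes, TAL1 was lower, at percentile 23.4. Of 16 histone genes, H1-4 (-1.23) was lower, at percentile 13.5. None of 30 cytosolic ribosomal protein genes, 26 oxidative phosphorylation genes or 5 fibroblast markers was counted, at percentiles 62.5, 37.0 and 43.9. RPL35A, counted as higher, is not in the ribosomal list. Only 2 genes of MHC class II, HLA-DMA (0.97) and CD74 (-0.83), were above the level minimum, too few for a list value.

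Of 30 lists with a value in SKBR-3, 8 stood apart, where 1.5 would by chance if the genes of a list varied independently. Of the other lists, cholesterol and replication stood apart as higher without a level minimum (percentiles 99.1 and 99.2), and cholesterol and the luminal markers by their mean (98.2 and 99.7). In simulated data with the spread seen between these 2 arrays, 1206 unchanged genes were counted, among 7844 simulated genes of which 200 had been changed. That spread holds real differences as well as noise, so the count follows from it and is no estimate of false counts. In the measured data, 27 genes exceeded 3 local SDs upward and 65 downward.

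In ZR-75-1, the knockdown array differed less from its control, with 75 genes counted as higher and 88 as lower of 7520 above the level minimum. RLN1, which encodes the peptide hormone relaxin 1, had an intensity of 918 against a dim 55.6 in the control, so the size of its ratio is uncertain. BMI1, a Polycomb gene, had a log2 ratio of 2.35, and SERP2 was 4.98-fold higher, the carboxylesterase gene CES1 4.21-fold and PIP, a secretory gene of apocrine epithelium, 3.92-fold. HLA-DRA (log2 ratio 1.90), BPIFB1 (1.72), PCDHB1 (1.64), KRT33B (1.61), ARHGAP24 (1.53), TNS2 (1.502) and PAPSS2 (1.498) made up the rest of the 12 largest increases. ARHGAP24 had 2 features, and their mean gave 0.45, under the threshold. The largest decreases were in LDHB, a lactate dehydrogenase subunit gene, with 124 against 1402, and NES, the intermediate filament gene nestin, with 230.0 against 2141. CSPG4 (-2.79), VPS35L (-2.54), the collagen receptor gene DDR2 (-2.15), AKR1C1 (-2.06), MAN2B1 (-1.96), CXCL8 (-1.86), OR56A1 (-1.85), SOSTDC1 (-1.84), TTLL3 (-1.83) and the transcription factor gene GATA6 (-1.70) followed. Ratios with 1 value below the level minimum are uncertain in size and rank here too. Such were the knockdown values of LDHB, NES, CSPG4 (139) and VPS35L (172) and the control values of BMI1 (181) and SERP2 (243), among others.

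The list of NF-κB targets, cytokines and chemokines was lower as a set in ZR-75-1. Of its 21 measured genes, 6 were counted as lower and 2 as higher. The neutrophil chemokine gene CXCL8 had an intensity of 226 in the knockdown and 821 in the control. CCL2 (-1.68), CXCL1 (-1.30), CCL20 (-1.10), the adhesion molecule gene ICAM1 (-1.17) and the growth factor gene CSF1 (-1.10) were also lower. LCN2 (1.32) and SAA2 (1.05), which encode acute-phase proteins, were higher. The list's median was -0.63, below all 10000 random lists. It stood apart under each alternative setting, but the median was only -0.29 with the 80th percentile minimum.

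**Figure D3:**
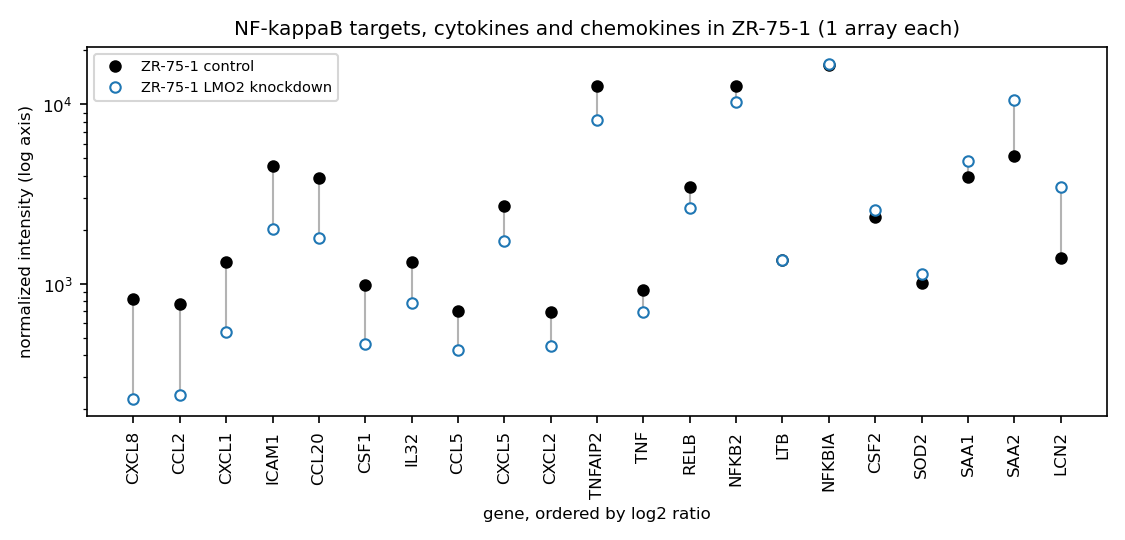
Points are the normalized intensities, on a log axis, of the 21 measured NF-κB targets, cytokines and chemokines on the ZR-75-1 control array (black) and the knockdown array (open blue), 1 array each, ordered by log2 ratio. CXCL8 at the left was 821 in the control and 226 in the knockdown, and LCN2 at the right was 1383 in the control and 3463 in the knockdown.

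Other lists that stood apart in ZR-75-1 did so through small shifts of uncounted genes. The 20 mitosis genes had a median of 0.20 at percentile 99.8, with CCNA2 (0.86), CENPF (0.72), KIF11 (0.70) and MKI67 (0.61) the furthest from 0. The 20 genes of cholesterol synthesis and LDL uptake had a median of 0.14 at percentile 99.6, with LSS at 0.79 and FDPS at 0.56. The 17 histone genes had a median of 0.18 at percentile 99.4, and the 11 HER2 genes one of 0.24 at percentile 99.3. The 31 cytosolic ribosomal protein genes had a median of -0.16 at percentile 0.79, with RPS2 (-0.68) and RPL18 (-0.63) low and RPS23 (0.74) high. The fibroblast list rested on 3 genes, with a median of 0.40 at percentile 97.6 and FBLN2 (-0.61) and FBLN1 (0.55) in opposite directions. None of the genes of these 6 lists was counted. The cholesterol list lay at percentile 92.2 with the 80th percentile minimum, the HER2 list at 96.7 with that minimum, the histone list at 93.4 by its mean, the ribosomal list at 5.42 without matching on level and the fibroblast list at 77.3 by its mean, each then no longer apart. Without a level minimum the HER2 list lay at percentile 89.8, and the fibroblast list had a median of -0.06 at percentile 35.2, so its direction turned.

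The remaining lists in ZR-75-1 lay within the range of random lists. Of 13 Wnt/β-catenin targets, MYC (-1.15) was lower, at percentile 89.98, and MYC was also the 1 counted gene of 16 immediate early genes, at percentile 3.04. Of 16 oestrogen response genes, IGFBP5 (-1.15) was lower, at percentile 3.79. Of 5 MHC class II genes, HLA-DRA was higher and CD74 (0.68), the invariant chain gene, was not counted, at percentile 96.5. No gene was counted among 15 p53 targets (percentile 3.79), 10 interferon-stimulated genes (10.4), 24 genes of Arp2/3 and actin turnover (9.23), 11 Wnt pathway components (43.9) or 10 LMO2 partners and LIM-only genes (48.4). None was counted among 21 replication genes (82.9), 13 genes of MHC class I (92.2), 16 luminal markers (50.1), 11 basal markers (83.1) or 7 mesenchymal genes (27.4). None was counted among 19 hypoxia and glycolysis genes (17.2), 12 fatty acid and lipid genes (93.0), 17 stress response genes (20.5), 13 heat shock chaperones (37.9) or 13 TGF-β and BMP targets (35.5). The same held for 8 Notch genes (44.4), 5 endothelial and haematopoietic genes (7.94), 3 immune markers (66.1), 26 oxidative phosphorylation genes (5.75) and 13 housekeeping genes (14.3). Some of these lists stood apart under other settings. The p53 targets, with GDF15 at -0.85 and BTG2 at -0.72, were then lower with quantile normalization (percentile 2.22), without a level minimum (1.08) and by their mean (0.80). The Arp2/3 and actin list was lower without a minimum (0.505) and with the 80th percentile minimum (0.995), and MHC class II was higher without a minimum (98.8), without matching (98.0) and by its mean (99.7). Under 1 setting each, the endothelial (1.23), oestrogen response (1.88) and oxidative phosphorylation (1.97) lists were lower and the fatty acid list (98.2) was higher. Of 31 lists, 7 stood apart, where 1.55 would by chance if the genes of a list varied independently. In simulated data with the spread of these 2 arrays, 37 unchanged genes were counted, among 7520 simulated genes of which 200 had been changed. That spread too holds real differences, so the count is no estimate of false counts.

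**Figure D4:**
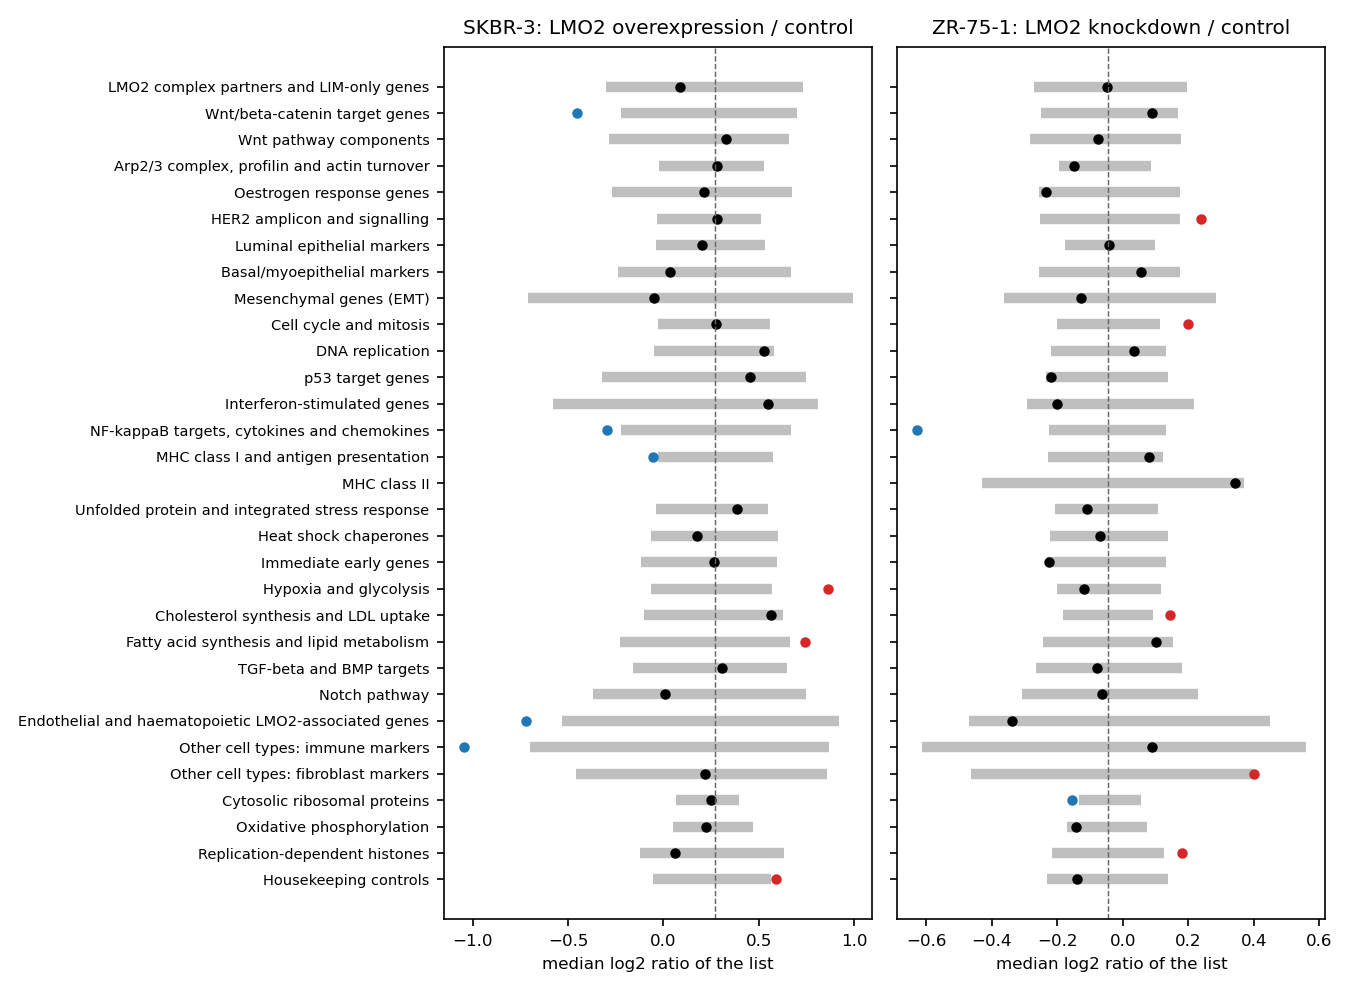
Each point is the median log2 ratio, treated over control, of the measured genes of 1 list in SKBR-3 (left) and ZR-75-1 (right), red where it stood apart as higher and blue where lower. Grey bars hold the central 95% of 10000 random lists matched on level, and the dashed line is the median of all genes above the level minimum, 0.27 in SKBR-3 and -0.05 in ZR-75-1. The NF-κB and chemokine list lies left of its bar in both panels, at -0.30 and -0.63.

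Genes counted in both lines were few. Of 6596 genes above the level minimum in both comparisons, 6 were higher with overexpression and lower with knockdown, where independent lists would share 6.55. Of these, BTG1, an antiproliferation gene, had log2 ratios of 1.49 and -1.48, SNCG 1.78 and -1.33, PRRG2 1.15 and -1.48 and the hyaluronidase gene HYAL1 1.15 and -1.07. A further 13 genes were lower with overexpression and higher with knockdown, where 2.19 would be shared, among them BPIFB1 (-1.96 and 1.72), KRT33B (-1.55 and 1.61), ZNF562 (-1.25 and 1.33), CDH22 (-1.13 and 1.496), the transcription factor gene FOXA2 (-2.16 and 1.11) and CD300LB (-1.15 and 1.08). In the same direction, 4 genes were higher in both, where 5.81 would be shared: the desmosomal gene DSG2 (1.72 and 1.49), GALNT12 (1.58 and 1.45), SLC37A3 (1.34 and 1.49) and ARHGAP24 (1.16 and 1.53). With the mean over the features of a gene, ARHGAP24 was under the threshold in ZR-75-1, and 3 genes were higher in both. Another 9 were lower in both, where 2.47 would be shared, among them CAMKV (-1.65 and -1.69), KRTAP9-2 (-1.22 and -1.20), KRT16 (-1.90 and -1.13), OR56A1 (-1.10 and -1.85), CLEC7A (-1.43 and -1.07) and LCE3B (-1.36 and -1.02). Across these 6596 genes, which are not independent replicates, Pearson's correlation of the 2 log2 ratios was -0.12 and Spearman's -0.12, and without a level minimum Pearson's was -0.035. At a 1.5-fold threshold 52 genes were lower in both, where 51.1 would be shared.

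The control arrays of both lines were compared to describe the lines and check their labels. Of 8164 genes, 1185 were counted as higher and 1856 as lower in SKBR-3 than in ZR-75-1. ERBB2 had an intensity of 27859 in SKBR-3 and 10989 in ZR-75-1, and its neighbour GRB7 had 11555 and 1890. Of 14 genes of the HER2 amplicon and signalling, 12 were counted as higher and 1 as lower, with GSDMB (5.17), CDK12 (3.81), MED1 (3.21) and MIEN1 (2.71) the furthest from 0 and a median of 1.77, above all random lists. The E-cadherin gene CDH1 had a dim 72.4 in SKBR-3 against 13579, and TFF1, an oestrogen-induced gene, had 130 against 1448. The 14 measured oestrogen response genes, with 1 counted as higher and 4 as lower, did not stand apart, at percentile 32.7. TFF1 alone is therefore a weak check of the labels. The feature of ESR1, the oestrogen receptor gene, lay between 33.4 and 58.4 on all 4 arrays, near their lowest intensities, and was uninformative. MGST1, OLFM4, SSX2, ERVW-1, PSG2, SSX4B, LGALS3BP (5.13), MALL, USP17L2, RIT2 and GPRC5A were also among the largest log2 ratios above 0. BRINP3, AKR1C1, PTDSS1, the chemokine gene CCL20, TSPAN8, CRYM, NME4, DEGS2, LGALS3, TFAP2B (-5.69) and TCEA3 were among the largest below 0. Of these genes, beyond the HER2 list, ratios are left out where the lower value lay below the level minimum, since their size and order are uncertain.

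Sterol, p53 and chemokine genes were lower in the SKBR-3 control than in the ZR-75-1 control. Of 20 genes of cholesterol synthesis and LDL uptake, 16 were counted as lower and 1 as higher, with INSIG1 at -3.49 and a median of -1.59, below all random lists. Of 12 fatty acid and lipid genes, 6 were lower and 0 higher, with SCD at -5.18 and a median of -1.01 at percentile 0.83. Of 15 p53 targets, 9 were lower and 0 higher, with the cell cycle inhibitor gene CDKN1A at -4.67 and a median of -1.37 at percentile 0.07, but at percentile 10.6 with the 80th percentile minimum. Of 21 NF-κB targets and chemokines, 9 were lower and 1 higher, with a median of -0.97 at percentile 0.985. Higher in SKBR-3 were the immune markers (5 of 8, median 1.47, percentile 99.8) and the fibroblast markers, with FBLN1 at 2.91 and FBLN2 at 2.89 (3 of 4, median 2.64, above all random lists). The basal markers had 6 of 13 higher and 3 lower (median 0.59, percentile 98.4), and lay at percentile 69.3 without a level minimum. The mitosis genes had 2 of 20 higher and 1 lower (median 0.35, percentile 97.51), and lay at 96.8 with quantile normalization. The other 22 lists lay between percentiles 8.41 and 96.1, but by the mean of a list 13 lists stood apart in place of 9, with 6 of these 22 among them. The SKBR-3 control array is the one on which the sensory, hair, skin, lens and defensin genes had the median of 265, and it enters this comparison as well as that with LMO2 overexpression.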

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

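The test of whether the SKBR-3 control array departs from the other arrays was chosen only after that result was seen, and the other tests were set before their values were computed, although some members of families typical of other tissues (silent families), and the value of CDH1, had been seen by then.

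SKBR-3 had 9.58 times as many counted genes as ZR-75-1, and a trend with level as the whole cause is argued against, since the ratio was still 9.08 after loess. The size of the excess depends on the rule: the totals were 3489 against 1111 without a level minimum and 3785 against 852 at 1.5-fold. With at least 3 local SDs the totals were 92 against 153, but that rule divides each ratio by the spread of its own comparison. The robust SD over genes above the level minimum was 0.71 in SKBR-3 and 0.33 in ZR-75-1. Such totals largely lose a difference in spread by construction and cannot be set against the excess. ZR-75-1 RNA making up 5% or more of the overexpression sample is argued against too: 6 genes strong in ZR-75-1 and dim in the SKBR-3 control had a median of 2.68% of their ZR-75-1 level there, against 1.44% on the control array, and CDH1 had 0.32%. Of the 6, 2 lay above 5%, the highest at 37.5%, but mixed-in RNA would add about the same share to each gene. These 2 genes are therefore no sign of a smaller share. The overexpression array correlated more with the ZR-75-1 control (Pearson's 0.906) than the SKBR-3 control did (0.864). An unusual SKBR-3 control array could give this too, so it does not decide. A smaller share is not excluded. A fault or unusual background of the SKBR-3 control array stays open, since genes of the silent families had a median log2 ratio of -0.74 in SKBR-3 and 0.01 in ZR-75-1. In 70.2% of the counted SKBR-3 genes the control value was the one farther from the ZR-75-1 mean, which restates the observation behind that test and decides nothing. For single features that fail on 1 array, the planned test could not tell. Of 83 further features of counted genes, 41, or 49.4%, changed the same way by at least 2-fold. The exact 95% interval, 38.2 to 60.6, treats features as independent. The same sign was seen in 80 of 83. That argues against isolated failures as the main source of these genes' ratios, unless features of a gene share sequence, which is not known here. For counted genes with 1 feature such failures stay open. In ZR-75-1, 3 of 11 further features, 27.3% (6.02 to 61.0), changed the same way by at least 2-fold, and 10 of 11 had the same sign. The 2-fold bar decides little, since the first feature of each gene had been selected at that size. An effect of LMO2 or of the derivation of the strains on many genes also stays open and was not tested, as each group is 1 array.

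The median log2 ratio of NF-κB targets, cytokines and chemokines was -0.30 with LMO2 overexpression and -0.63 with knockdown, the same sign under opposite treatments of LMO2. The medians rested on 13 and 21 members, which were not all the same genes. TNFAIP2 was lower on both treated arrays, but SAA2 had log2 ratios of -1.68 and 1.05. CXCL8, the list's largest decrease in ZR-75-1, was dim in SKBR-3, at 69.8 with overexpression and 56.8 in the control. The shared sign therefore does not show that the same genes were lower in both lines. With the 80th percentile minimum the values were -0.72 and -0.29, so their order of size is not settled, and the difference between lines was not tested. For the decrease in ZR-75-1, a trend with level is argued against, since the median was -0.59 after loess and still below the random lists' range. Cross-hybridisation among CXCL1, CXCL2, CXCL3, SAA1 and SAA2 is argued against, since the median without them was -0.63 over 17 genes. Noise near the level minimum is argued against, since the median was -0.29, at percentile 0.905, over 11 genes above the 80th percentile minimum. An effect of LMO2 knockdown stays open and was not tested on 1 array per group, as do differences in culture density, clone selection and off-target effects of the shRNA.

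Opposite treatments of LMO2 gave 9 genes counted as lower in both lines and 4 as higher in both, with no test of the difference between lines. Genes lower in SKBR-3 and counted in ZR-75-1 in either direction numbered 22, which is 4.71 times the 4.67 of independent lists. A trend between the SKBR-3 arrays is argued against as the whole cause, since the ratio was 3.18 after loess, and so is noise near the level minimum, since it was 6.92 with the 80th percentile minimum, though on 5 genes. Of the 9 genes lower in both lines 3 belong to the silent families, and of the 13 lower in SKBR-3 and higher in ZR-75-1 none do, beside 52 of all 566 genes lower in SKBR-3. Other genes typical of other tissues can lie outside these 6 families. The absence of members among the 13 therefore does not show that the 13 are free of a raised SKBR-3 control signal. The excess held for both directions in ZR-75-1 at 2-fold, but at 1.5-fold it held for the opposite direction (86 against 33.5) and not for the same one (52 against 51.1), and its source stays open.

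Unnamed features, which entered no comparison of genes, also differed: 1374 were at least 2-fold higher and 1617 lower in SKBR-3 with overexpression, of 11982 above the level minimum. In ZR-75-1 with knockdown, 148 were higher and 128 lower, of 11019.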

How the results depend on the processing

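All settings here were planned. Quantile normalization and loess moved the median of genes above the level minimum in SKBR-3 by -0.10 and -0.12 on the log2 scale. They kept 1399 and 1335 of the 1562 counted genes, and gave 57.4% and 55.6% of counted genes as higher, against 63.8%. No named gene that was counted changed its sign under an alternative. Of 142 genes picked by the naming rule in SKBR-3, 6 were no longer counted after loess and 6 were newly counted. With quantile normalization these were 3 and 5, and with the mean over the features of a gene 6 and 3. Ratios close to the 2-fold threshold therefore depend on the setting. The counts follow from the thresholds by construction. Without a level minimum, 1936 genes were higher and 1553 lower in SKBR-3 with overexpression, 542 and 569 in ZR-75-1 with knockdown, and 2433 and 2963 between the controls. The genes of both treated comparisons were then 50 (higher, higher), 52 (higher, lower), 82 (lower, higher) and 90 (lower, lower), with overexpression named first, Pearson's correlation was -0.035, and 5 lists stood apart in SKBR-3 in place of 8. With the 80th percentile as minimum the counts were 445 and 202, 24 and 28, and 572 and 1080, the overlaps 0, 3, 4 and 1 in the same order, and 5 lists stood apart in SKBR-3. At 1.5-fold the counts were 2454 and 1331, 368 and 484, and 2033 and 2947, with overlaps of 53, 122, 86 and 52. At 3-fold they were 188 and 132, 9 and 16, and 517 and 895, with overlaps of 0, 0, 1 and 1. With at least 3 local SDs, SKBR-3 had 27 higher and 65 lower, so the direction of the majority changed, the controls had 125 and 138, and the overlaps were 0, 0, 3 and 0. ZR-75-1 then had 88 higher and 65 lower in place of 75 and 88, and 102 of its 163 genes were shared.

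In SKBR-3 the hypoxia and NF-κB lists stood apart under every list setting, and the immune list under every one but the 80th percentile minimum, which left too few of its genes. With no level minimum 5 lists no longer stood apart. These were the fatty acid (percentile 83.7), Wnt target (5.19), MHC class I (3.39), endothelial (2.81) and housekeeping (97.3) lists. The Wnt targets also lay at 3.02 by their mean and at 9.67 with the mean over the features of a gene. With no matching the MHC class I list lay at 8.78 and the housekeeping list at 94.2. The cause was not tested. In ZR-75-1 the NF-κB and mitosis lists stood apart under every list setting. LMO2 had log2 ratios of 1.18 and -2.60 with quantile normalization. No paired analysis was possible because each group has 1 array and no test was run, and leaving out the SKBR-3 control array leaves no control for that line. The number of arrays limits the precision of these comparisons, and LMO2 itself lies below the level minimum.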

Other observations

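The genes of the first paragraph were chosen after their values were seen, and the list of NRF2 targets was written after that, before its median was computed.

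AKR1C1, AKR1C2, AKR1C3 and AKR1C4, which encode steroid- and carbonyl-reducing enzymes, were counted as lower in the ZR-75-1 knockdown array. AKR1C1 had an intensity of 928 against 3878 in the control, and the log2 ratios were -2.06 for AKR1C1, -1.66 for AKR1C2, -1.46 for AKR1C4 and -1.001 for AKR1C3. These genes are highly similar in sequence, so their features may not be independent. HMOX1, the haem oxygenase 1 gene, was lower as well, at -1.21. AKR1C genes and HMOX1 are both known targets of the transcription factor NRF2, which gave the hypothesis that NRF2 targets were lower as a set. Among 25 other targets, 16 were above the level minimum, 0 were counted in either direction, and their median was -0.18 at percentile 5.34 of random lists. A decrease of the whole set of the size seen in AKR1C genes is argued against, and a small one is not excluded.

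SCD, ACSS2 and FASN, the lipid genes named as higher with LMO2 overexpression in SKBR-3, had levels there between those of the SKBR-3 and ZR-75-1 controls. SCD had an intensity of 620.4 in the SKBR-3 control, 3867 with overexpression and 22545 in the ZR-75-1 control. ACSS2 had 972, 4351 and 5035, and FASN had 10875, 32435 and 36026. Both comparisons of these genes share the SKBR-3 control array, so a value peculiar to that array moves both.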
